A study of Homo sapiens with 4 samples.

How the data were processed

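RNA was measured in 4 libraries of the SUDHL4 lymphoma cell line, 2 control and 2 stimulated with megaCD40L and the IgM/G reagent. The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library. Per the submitters' processing notes, bcl2fastq, TopHat and HTSeq were used with the human build hg19 (GRCh37). Versions, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be separated with certainty. The reference at hand was of another build, so no coordinates are given, and genes are identified by the symbols of the deposited table.

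The table held 25559 gene rows and 5 HTSeq summary rows that name no gene. The summary rows took 26.9% and 26.5% of reads in control replicates 1 and 2, and 32.3% and 26.6% in stimulated replicates 1 and 2, and were left out of library sizes and tests. A set of 26 symbols had been turned into dates before deposit and cannot be assigned to genes with certainty. Through current and older names, 22382 symbols matched a reference gene table and 3177 did not. Each column was assigned to its sample by its name, and no column was left over. Groups came from the sample titles. Each pair of libraries differed by more than sampling noise (chi-square per gene 9.45 for the controls and 58.7 for the stimulated libraries), so neither pair was taken for 1 library deposited more than once, which leaves open whether the libraries are technical repeats.

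Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10), which left 12932, and libraries were scaled by TMM. Stimulated and control libraries were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common dispersion was 0.0241, a biological coefficient of variation of 15.5%. Values are CPM with TMM scaling, as mean ± SD over n = 2, or log2 fold changes ± SE, where the SE was the fold change divided by the root of the F statistic. CPM are relative to the reads counted in a library, so a change in total RNA per cell would not show in them. Where all control libraries had 0 counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% interval is given. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

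Fixed before the data were examined were 25 gene lists, which cover NF-κB targets, immediate-early and MAPK feedback genes, germinal-centre, dark-zone, light-zone, costimulation, MHC class II and class I, B cell receptor, plasma cell, chemokine and cytokine, BCL2 family, G2/M, S phase, MYC and ribosome biogenesis, cholesterol, glycolysis, oxidative phosphorylation, interferon, unfolded protein response, T cell, myeloid, NK cell, epithelial and stromal, and mitochondrial genes. The 21 lists with at least 5 tested members were tested with limma 3.58.1's camera (preset correlation 0.01, two-sided), adjusted over those lists. Genes were named by a rule fixed at the same time: the 8 largest rises and 8 largest falls among genes past the threshold with at least 10 CPM in the higher group and separated libraries, the 3 members with the smallest p from each list camera called and 2 from each other tested list, and 12 genes named in advance, 77 in all. Members named because they went against their list or were few were chosen after their values were seen. A few of the genes these rules select are not reported here.

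The fit was tested on simulated counts with the means and library sizes of these libraries, for stimulated against control with 2 libraries each over 12713 genes. It recovered 26% of genes changed 1.5-fold, 80% at 2-fold and 100% at 4-fold and at 8-fold. In the simulation 50 genes were changed at each fold size, a far smaller share than the 38.9% that passed in the data. With fewer changed genes the adjusted threshold is harder to reach, so these shares need not hold for the data. Of 181 calls in the simulation, 28 (15.5%) were false, more than the nominal share, and 5.2% of unchanged genes had an unadjusted p under 0.05. Camera called 0 of 20 unchanged lists. Those lists held randomly drawn genes that were simulated independently, so they do not test lists of correlated genes. In the data, the estimated correlation reached 0.639 for the S phase list. Alternatives planned beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no low-count filter, at least 5 CPM in 2 libraries, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. A correction for transcript GC content, with GC taken from GENCODE 29 transcripts and a loess span of 0.3, was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.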

Results

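Messenger RNA levels were measured by RNA sequencing in SUDHL4, an established human cell line of diffuse large B-cell lymphoma, a cancer of mature B cells. CD40 is a receptor through which T cells activate B cells, and megaCD40L is a multimeric form of its ligand. The stimulated cultures received megaCD40L at 100 ng/mL together with a reagent labelled IgM/G at 3.33 ug/mL, and were collected after 24 h. Control cultures were grown in plain medium. There were 2 libraries per group. The libraries held 27549224 and 25915032 reads in genes for control replicates 1 and 2, and 29839966 and 25916410 for stimulated replicates 1 and 2. A count of 3 corresponded to between 0.1005 and 0.1158 CPM, the count scaled to library size, per library, the level below which a transcript could not be told from absent by counting error alone. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

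The comparison of stimulated with control cells asks which transcripts differ after 24 h with both reagents. No collection time is given for the controls, so effects of time in culture cannot be separated from those of the reagents. No library received only 1 of the reagents, so their effects cannot be told apart either. Most tested NF-κB pathway, chemokine, costimulation and antigen presentation genes rose, and most cell division and ribosome biogenesis genes fell. As lists, the chemokine, MHC class I, G2/M, S phase and ribosome biogenesis genes no longer stood apart from other genes with an estimated correlation (camera adjusted p = 0.0682, 0.0682, 0.147, 0.398 and 0.184). The estimated correlation of the MHC class I list, −0.036, was below the preset 0.01, so correlation between its genes cannot explain its loss. That setting weakened the NF-κB list too (camera adjusted p = 4.49e-51, and 0.0393 with an estimated correlation). CD40 itself went from 29.8 ± 1.26 CPM in control to 210 ± 1.49 CPM in stimulated cells (SD, n = 2 each), while MYC, a transcription factor that drives growth, went from 668 ± 2.57 to 146 ± 53.0 CPM. Of 12932 genes tested with edgeR's quasi-likelihood test, 2707 rose and 2320 fell at a Benjamini-Hochberg adjusted p under 0.05, together 38.9% of the genes. Changes of at least 2-fold were more often rises, with 1705 genes up and 820 down. In 9291 genes (71.8%) both stimulated libraries lay beyond both control libraries, where chance gives 33.3%. The pair of stimulated libraries differed more from each other (SD of the log2 difference over genes 0.528) than the pair of control libraries did (0.396), and their difference followed the GC content of the transcript. The counts of calls depended on single libraries. Without control replicate 1, 1755 genes rose and 1294 fell, and without control replicate 2, 1768 rose and 1187 fell. Without stimulated replicate 1, 3685 rose and 3507 fell, and without stimulated replicate 2, 3885 rose and 3698 fell.

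**Figure D1:**
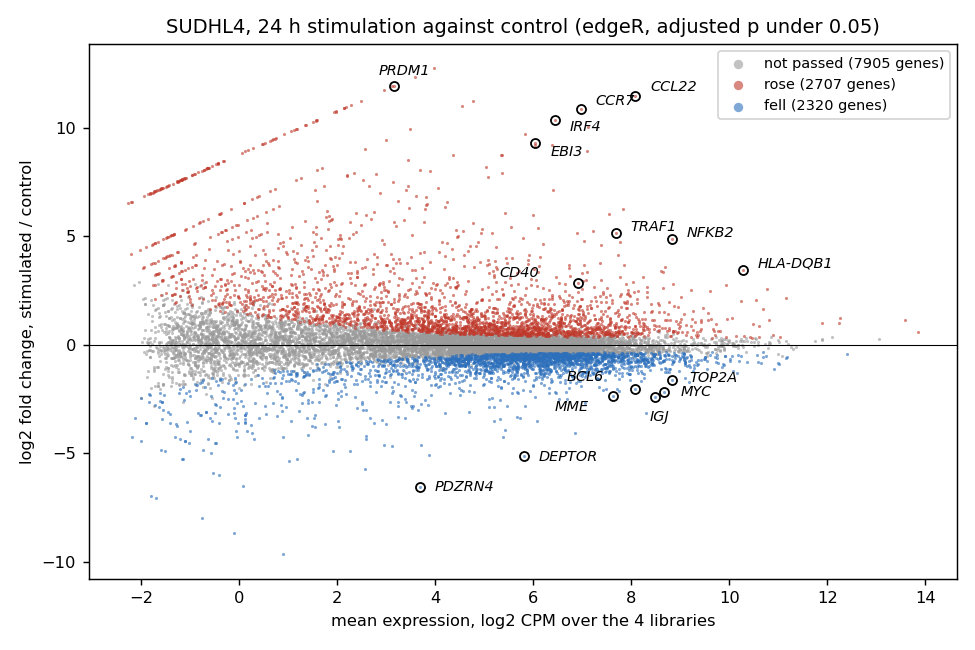
Each point is 1 of 12932 genes, with its mean expression in log2 CPM over the 4 libraries on the x axis and its log2 fold change of stimulated over control on the y axis. Red points (2707) rose and blue points (2320) fell in edgeR's test, and the diagonal lines of points at the upper left are genes at or near 0 counts in the control libraries, whose fitted fold changes depend on the prior count.

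**Figure D2:**
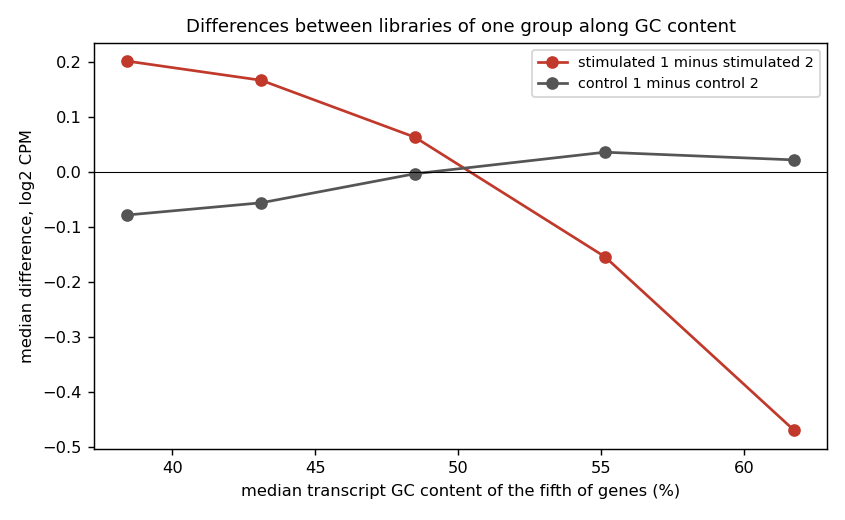
Median log2 CPM difference between the libraries of a group (y axis) for genes in 5 equal bins of transcript GC content (x axis, percent). The stimulated pair (red, replicate 1 minus replicate 2) runs from 0.20 at a median GC of 38.4% to −0.47 at 61.7%, and the control pair (grey) from −0.078 to 0.022.

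The largest rises were in genes that were nearly silent in control cells. CACNA1E, a calcium channel subunit, had no counts in either control library and reached 31.2 ± 25.8 CPM, at least 594-fold higher against a floor of 3 counts over the control group. On the same floor, the chemokine CCL3 was at least 437-fold higher (23.9 ± 4.08 CPM), PRDM1, which encodes the plasma cell regulator BLIMP1, at least 334-fold higher (17.8 ± 10.5 CPM), MDFIC at least 327-fold higher (17.5 ± 9.92 CPM), DUSP4, a phosphatase of MAP kinases, at least 292-fold higher (15.5 ± 9.86 CPM), and TNFRSF1B, the TNF receptor 2 gene, at least 203-fold higher (11.2 ± 0.717 CPM). Without stimulated replicate 1, the bounds fell to at least 235-fold for CACNA1E, 187-fold for PRDM1, 189-fold for MDFIC and 154-fold for DUSP4. The chemokine CCL22 went from 0.183 ± 0.043 to 542 ± 350 CPM, with values from both stimulated libraries far above control but apart from each other. CD44, an adhesion receptor, had 1 count in the control group and 54.5 ± 42.3 CPM in stimulated cells, a ratio of 3102 with an exact 95% counting interval of 556 to 122600, or a ratio of 1332 without stimulated replicate 1. The adjusted p of these 8 genes in edgeR's test ran from 4.51e-05 (CCL3) to 0.00134 (CACNA1E). Altogether 97 of the genes that rose had no counts in the control libraries.

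Large falls among well expressed genes were those of PDZRN4 (log2 fold change −6.55 ± 0.37 SE), DEPTOR (−5.14 ± 0.22), which encodes an inhibitor of mTOR, and WNK2 (−5.11 ± 0.55). RAP1GAP2 (−4.66 ± 0.67), ACY3 (−4.62 ± 0.28), FNDC1 (−4.61 ± 0.29) and FHOD3 (−4.25 ± 0.33) followed. DEPTOR went from 109 ± 3.49 to 3.09 ± 0.886 CPM, and PDZRN4 from 25.7 ± 0.126 to 0.260 ± 0.198 CPM. The size of 4 of these falls depended on the library: without stimulated replicate 1 or 2 in turn, the log2 fold change was −7.70 or −5.99 for PDZRN4, −4.28 or −6.90 for WNK2, −3.71 or −7.31 for RAP1GAP2 and −3.81 or −4.86 for FHOD3. The adjusted p in edgeR's test ran from 1.93e-05 (DEPTOR) to 0.00207 (RAP1GAP2).

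All 28 measured members of the list of NF-κB targets and regulators rose, and all 28 passed when adjusted over the list alone. TRAF1, an adaptor of TNF receptors, went from 11.4 ± 0.376 to 400 ± 25.5 CPM (log2 fold change 5.14 ± 0.15 SE), NFKB2, which encodes a subunit of NF-κB, from 30.2 ± 1.32 to 886 ± 133 CPM (4.87 ± 0.16), and NFKBIA, which encodes its inhibitor IκBα, from 9.26 ± 0.167 to 92.1 ± 5.23 CPM (3.31 ± 0.15). EBI3, a cytokine subunit, went from 0.206 ± 0.141 to 132 ± 0.480 CPM. The median log2 fold change of the list was 2.98, and limma's camera test set it apart from the other genes (adjusted p = 4.49e-51). Of 25 immediate-early and MAPK feedback genes in the file, 22 could be tested: 20 rose, MYC fell and FOSB, at 3.27 CPM in control and 10.2 CPM in stimulated cells, did not pass. Adjusted over the list alone, 21 rose and 1 fell. Among those that rose, EGR2 had a log2 fold change of 9.72 ± 0.30, and the MAP kinase phosphatase genes DUSP5 and DUSP2 had 4.66 ± 0.20 and 3.13 ± 0.15. The list median was 3.16 (camera adjusted p = 8.12e-21).

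**Figure D3:**
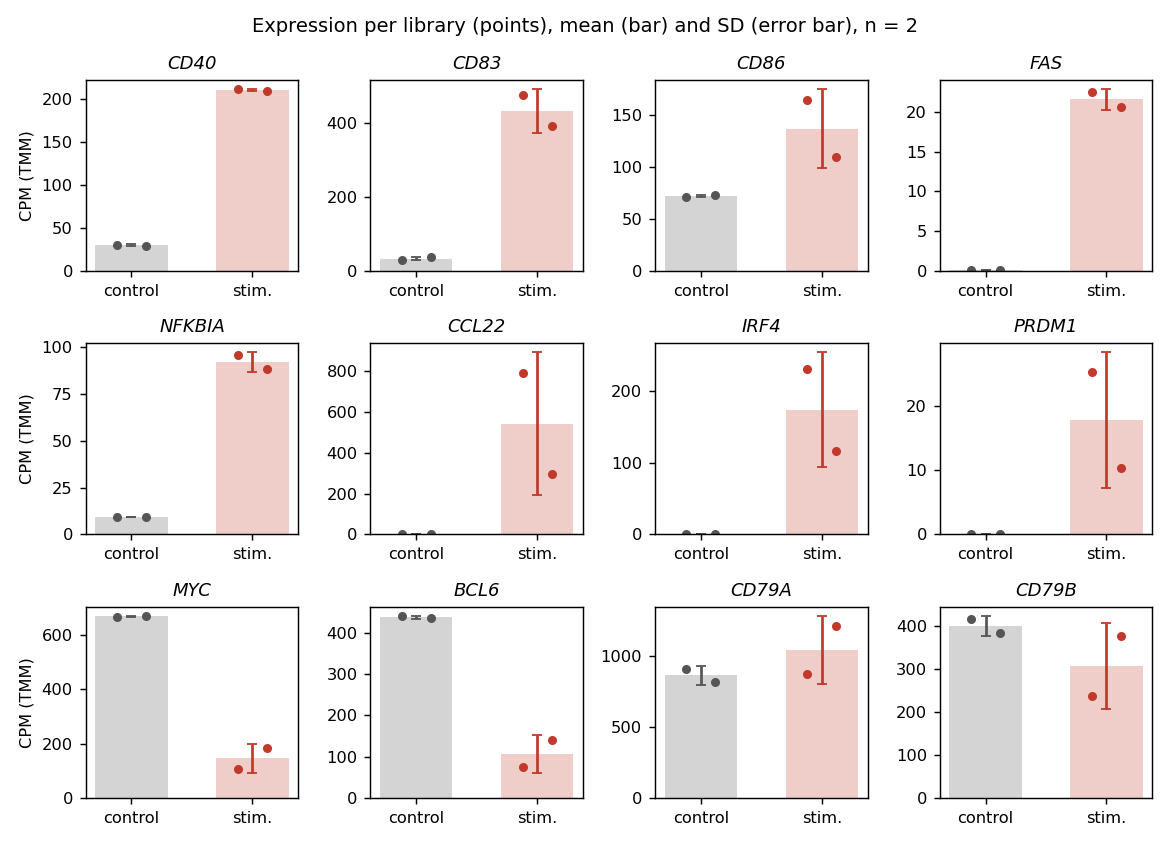
CPM of the 12 genes named in advance, per library (points), with the group mean (bar) and SD (error bar, n = 2). CD40 reached 210 CPM in stimulated cells with a narrow spread, MYC and BCL6 were lower in both stimulated libraries, and CD79A and CD79B did not pass the test.

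Light-zone and CD40-activated genes, which mark germinal-centre B cells receiving T cell help, rose in 19 of 20 cases, with MYC the 1 that fell, and the counts were equal when adjusted over the list alone. The list median log2 fold change was 4.51 (camera adjusted p = 9.03e-52). The activation marker CD83 went from 33.4 ± 5.18 to 432 ± 59.4 CPM (log2 fold change 3.69 ± 0.18), and IRF4, a transcription factor of activated B cells and plasma cells, from 0.130 ± 0.033 to 174 ± 80.5 CPM (10.35 ± 0.52, leave-one-out 9.76 to 10.76). Costimulation and adhesion molecules rose in 17 of 21 cases, SLAMF6 fell (log2 fold change −1.41 ± 0.18), and ICAM3, ITGAL and ITGA4 did not pass. Counts adjusted over the list alone were again 17 and 1. FAS, which encodes a death receptor, rose by 7.33 ± 0.31 on the log2 scale, TNFRSF14 by 5.26 ± 0.22, SLAMF1 by 4.93 ± 0.21 and CD86, a ligand of CD28 on T cells, by 0.93 ± 0.19 (edgeR adjusted p = 0.00942). Over the list, the median was 2.82 (camera adjusted p = 2.18e-21).

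Genes of antigen presentation rose as well. In the MHC class II list, 15 of 18 members rose, RFXAP fell (−0.93 ± 0.15), and HLA-DOB and RFXANK did not pass. CIITA, the transactivator of class II genes, went from 71.0 ± 7.36 to 729 ± 40.1 CPM, HLA-DQB1 from 211 ± 6.24 to 2287 ± 241 CPM and HLA-DRB1 from 254 ± 4.86 to 1691 ± 103 CPM. Camera called the list (median 2.05, adjusted p = 8.19e-21). In the MHC class I list 13 of 18 rose, PDIA3 fell (−0.76 ± 0.12), and TAP2, PSMB8, ERAP2 and CALR did not pass. HLA-B rose by 4.73 ± 0.19, HLA-E by 3.42 ± 0.14 and HLA-C by 3.30 ± 0.16 on the log2 scale, and the list median was 0.98 (camera adjusted p = 2.07e-09, and adjusted p = 0.0682 with an estimated correlation). Counts adjusted over the list alone were equal for both lists. HLA genes share reads with near-identical paralogs and vary in sequence between genomes, so the size of each one's change is uncertain.

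Of 32 chemokines, cytokines and their receptors in the file, 23 could be tested and 21 of these rose, also when adjusted over the list alone, while IL4R and CXCR4 did not pass. The other 9 had no counts in control and at most 9 counts in stimulated cells. CCR7, a receptor that guides lymphocytes into lymph nodes, went from 0.127 ± 0.072 to 250 ± 83.7 CPM (log2 fold change 10.87 ± 0.42, leave-one-out 10.41 to 11.58), and LTA, which encodes lymphotoxin alpha, from 1.26 ± 0.219 to 84.5 ± 14.1 CPM. The list median was 5.42, or 5.26 with the 6 members at 0 in control set to their lower bound (camera adjusted p = 3.88e-35, and adjusted p = 0.0682 with an estimated correlation).

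Of 29 B cell receptor signalling components, 18 rose and BTK, PLCG2 and FCGR2B fell (log2 fold changes −0.43 ± 0.12, −0.54 ± 0.14 and −1.59 ± 0.19), with 18 and 4 adjusted over the list alone. FCRL5, a receptor of the Fc receptor-like family, went from 0.180 ± 0.1999 to 81.5 ± 6.03 CPM, PTPN6, which encodes the phosphatase SHP-1, from 13.3 ± 0.827 to 321 ± 8.46 CPM, and PIK3CD, a catalytic subunit of PI3 kinase, from 82.2 ± 5.25 to 449 ± 7.11 CPM. The 2 signalling chains of the receptor did not pass: CD79A was at 862 ± 64.9 CPM in control and 1039 ± 240 CPM in stimulated cells (edgeR adjusted p = 0.236), and CD79B at 401 ± 23.6 and 308 ± 99.5 CPM (adjusted p = 0.192). Both depended on single libraries. CD79A passed without stimulated replicate 1 (log2 fold change 0.47), CD79B passed without stimulated replicate 2 (−0.75) and with a correction for GC content (−0.55). Across the 29 genes the median was 0.62 (camera adjusted p = 1.70e-06, and adjusted p = 0.108 with an estimated correlation). Among 16 apoptosis regulators of the BCL2 family, 9 rose and none fell, also over the list alone. They include genes that oppose cell death, BCL2A1 (5.35 ± 0.29) and BCL2L1 (1.77 ± 0.13), and HRK, which promotes it (5.11 ± 0.35). The list median was 0.64 (camera adjusted p = 6.10e-05, and adjusted p = 0.111 with an estimated correlation). That correlation was −0.037, below the preset 0.01.

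Genes of B cell identity moved in both directions. Of 27 germinal-centre B cell genes, 8 rose and 11 fell (9 and 12 adjusted over the list alone), and camera did not call the list (median −0.21, adjusted p = 0.188), though it did without control replicate 1 (0.0225) or control replicate 2 (0.0183). BCL6, a transcriptional repressor that maintains the germinal-centre state, went from 437 ± 3.86 to 107 ± 46.2 CPM (log2 fold change −2.04 ± 0.27, edgeR adjusted p = 0.00149), and MME, which encodes the surface marker CD10, from 334 ± 10.3 to 64.3 ± 6.33 CPM. CXCR5, a chemokine receptor of follicular B cells, rose from 57.2 ± 5.04 to 273 ± 0.054 CPM. Of 13 dark-zone genes, 3 rose and 6 fell, also over the list alone (median −0.30, camera adjusted p = 0.0078, and adjusted p = 0.339 with an estimated correlation). Those that fell include KIF20A (−2.22 ± 0.15), PLK1 (−1.56 ± 0.16) and AURKA (−1.51 ± 0.13), which are mitotic genes, whereas those that rose include FOXP1 and GCET2. The camera call was lost without stimulated replicate 2 (adjusted p = 0.110). Of 17 plasma cell differentiation genes, 7 rose and 6 fell, also over the list alone. Beside the rises of PRDM1 and IRF4, IGJ, which encodes the joining chain of secreted antibodies, fell from 603 ± 19.2 to 112 ± 9.74 CPM. Camera gave no call (adjusted p = 0.497), and the list's median, −0.12, and mean, 1.64, had opposite signs.

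Cell division genes fell together. All 30 G2/M genes fell, also over the list alone, with a median log2 fold change of −1.35. TOP2A, a topoisomerase of dividing cells, went from 693 ± 24.7 to 223 ± 3.48 CPM, and CENPF, a kinetochore gene, from 444 ± 10.8 to 140 ± 1.52 CPM. Camera gave an adjusted p of 3.23e-22, and adjusted p = 0.147 with an estimated correlation. Of 33 S phase and DNA replication genes, 24 fell and none rose (25 fell and 1 rose adjusted over the list alone), with RFC3 at −1.595 ± 0.15, RRM2 at −1.23 ± 0.14 and GINS1 at −1.16 ± 0.13 (list median −0.81, camera adjusted p = 2.24e-08, and adjusted p = 0.398 with an estimated correlation). Of 32 MYC targets and ribosome biogenesis genes, 25 fell and PPAN rose (26 and 1 adjusted over the list alone). NCL, which encodes nucleolin, went from 2641 ± 62.5 to 1214 ± 7.68 CPM, HSPD1 from 1636 ± 66.7 to 664 ± 89.0 CPM and ODC1 from 1245 ± 35.04 to 609 ± 35.6 CPM (list median −0.75, camera adjusted p = 2.87e-08, and adjusted p = 0.184 with an estimated correlation).

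**Figure D4:**
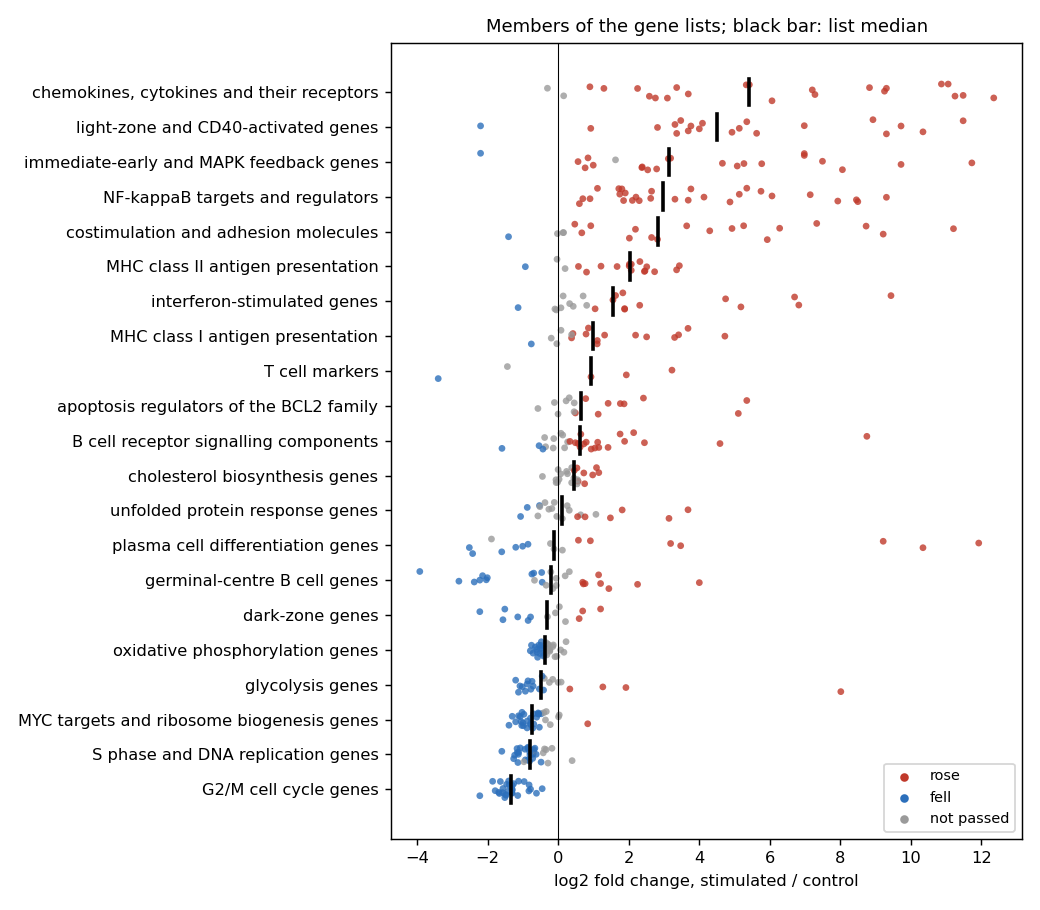
Log2 fold change of stimulated over control (x axis) for each measured member of the 21 tested gene lists (rows), with the list median as a black bar. Members are red where they rose, blue where they fell and grey where they did not pass, and the medians run from 5.42 for chemokines, cytokines and their receptors to −1.35 for G2/M genes.

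Of 34 oxidative phosphorylation genes, 16 fell and none rose (17 fell adjusted over the list alone), such as ATP5B (−0.75 ± 0.10), NDUFV2 (−0.71 ± 0.12) and NDUFS1 (−0.60 ± 0.12), with a list median of −0.38 (camera adjusted p = 0.00111, and adjusted p = 0.347 with an estimated correlation). NDUFS1 no longer passed without control replicate 1 (edgeR adjusted p = 0.111) or control replicate 2 (0.0885), and NDUFV2 without control replicate 2 (0.0652). Of 22 glycolysis genes, 13 fell and 4 rose, also over the list alone. LDHA, which encodes a subunit of lactate dehydrogenase, fell from 1511 ± 131 to 656 ± 84.9 CPM, while the glucose transporter gene SLC2A3 rose from 0.108 ± 0.099 to 29.8 ± 6.997 CPM and ALDOC from 5.21 ± 0.206 to 19.8 ± 3.55 CPM. Camera called the list lower (median −0.49, mean 0.0069, adjusted p = 0.0256, and adjusted p = 0.521 with an estimated correlation), so the mean lay on the other side of 0. Of 23 cholesterol biosynthesis genes, 9 rose and none fell (12 rose adjusted over the list alone), among them FDFT1 (1.15 ± 0.13) and MVD (1.09 ± 0.20), and camera did not call the list (median 0.45, adjusted p = 0.0854). It passed without control replicate 2 (0.0444), stimulated replicate 1 (0.00477) or stimulated replicate 2 (0.0131), with limma-voom (0.00518), without the low-count filter (0.0214) and with the GC correction (0.0422), but gave adjusted p = 0.398 with an estimated correlation.

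Of 37 interferon-stimulated genes in the file, 21 could be tested: 12 rose and ISG20 fell (log2 fold change −1.13 ± 0.18), also over the list alone. IFIH1, which encodes a sensor of viral RNA, went from 0.241 ± 0.038 to 27.7 ± 5.08 CPM and PARP9 from 18.7 ± 0.428 to 58.0 ± 1.38 CPM, whereas ISG15, at 22.5 CPM in control and 30.4 CPM in stimulated cells, did not pass. The list median was 1.56 (camera adjusted p = 9.09e-06, and adjusted p = 0.147 with an estimated correlation). Of 21 unfolded protein response genes, 6 rose and HSPA5, PDIA4 and MANF fell, also over the list alone, and camera gave no call (median 0.12, adjusted p = 0.388). PPP1R15A rose by 3.14 ± 0.13 and HERPUD1 by 1.82 ± 0.18 on the log2 scale. In all, camera called 16 of 21 lists, 10 higher and 6 lower. With an estimated correlation it called 5, each at an adjusted p of 0.0393: the NF-κB, immediate-early, light-zone, costimulation and MHC class II lists. Except for the MHC class II list, these lists share members, so their calls are not independent. The light-zone list shares TRAF1 and EBI3 with the NF-κB list, EGR2 with the immediate-early list and CD40 with the costimulation list.

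Markers of other cell types were mostly at or near 0. Of 16 T cell markers in the file, 5 could be tested: 3 rose, among them LCK (0.93 ± 0.16) and LAT (1.93 ± 0.23), CD247 fell (−3.40 ± 0.65) and CD3E, at 1.81 CPM in control and 0.676 CPM in stimulated cells, did not pass (3 rose and 2 fell adjusted over the list alone). Camera did not call the list (median 0.93, adjusted p = 0.433). Of 18 myeloid markers 2 could be tested and both rose, CSF1R to 1.11 CPM and CD68, a lysosomal protein gene, to 13.6 CPM. Of 11 NK cell markers PRF1 rose to 1.36 CPM and NKG7, at 0.816 CPM in stimulated cells, did not pass. Of 15 epithelial and stromal markers, VIM rose to 11.9 CPM and PDGFRB to 0.746 CPM, while DCN fell from 73.1 to 6.87 CPM and PECAM1 from 1.999 to 0.180 CPM. The median of these 4 was 1.96, or 0.15 with PDGFRB, at 0 in control, set to its lower bound. These last 3 lists had fewer than 5 tested members and no list test, and counts adjusted over the list alone were equal. None of the mitochondrially encoded transcripts of the last list was in the count table (0 symbols).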

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

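The tests of GC content and of a larger response between the stimulated libraries, and the test of a smaller share of cycling cells, were chosen only after the results were seen.

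The share of reads with more than 1 alignment, counted in an HTSeq summary row that the gene tests do not use, was above both controls (9.18% and 10.1%) in stimulated replicate 1 (14.4%) and stimulated replicate 2 (10.6%).

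Stimulated replicates 1 and 2 differed from each other gene by gene (SD of the log2 difference 0.528, against 0.396 for the controls), and the difference followed GC content, with Spearman's rho of −0.558 over 11998 genes, which are not independent replicates, against 0.201 for the control pair. Unequal depth is argued against, since thinning all libraries to 25915032 reads left the SD at 0.529, against 0.394 for the controls. A larger response in stimulated replicate 1 does not account for the GC trend, because the fold change itself rose with GC content (rho 0.132). Whether a larger response adds to the rest cannot be told apart from other sources of spread: with the GC trend removed, the median difference was 0.097 (bootstrap SE 0.0075) over genes that rose, −0.189 over genes that fell and −0.042 over the others, and 65.1% of risen genes were higher and 79.9% of fallen genes lower in stimulated replicate 1, which goes the way of a larger response, but the first median lay inside a bound of 0.1, set after the values had been seen, by less than its SE. That bound first read as excluding a larger response, and the SE was added afterwards. A later test against the other genes came out in favour of a larger response. It was set aside because it was written to replace the first. The SE came from resampling genes, which are not independent, so it does not measure the spread between libraries. A GC-dependent library bias is a candidate explanation for part of the difference, and removing the trend lowered the SD to 0.461.

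All 30 G2/M genes fell. A few genes taking more of the counts would lower all other genes alike, but the list median minus that of all genes was −1.386, a difference that no scaling of whole libraries can move. A GC-dependent bias is argued against, since with the GC correction the list median was −1.339. In the stimulated cultures, a smaller share of cycling cells and lower levels of these transcripts per cycling cell both stay open. They cannot be told apart. Of S phase members, 87.9% were below both controls in both stimulated libraries. However, the fall of both lists had been seen before that test was chosen.

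SIRPA, a receptor better known from myeloid cells and chosen here after its values were seen, went from 18 to 4587 counts (82.4 ± 13.9 CPM in stimulated cells, SD, n = 2), and CCR7 from 7 to 14068 counts. Myeloid cells in the stimulated cultures would bring their abundant transcripts, but LYZ, S100A8 and S100A9 had no counts in any library, and the highest gain of 5 myeloid transcripts was 0 of SIRPA's gain. Of the myeloid list, CD68 and CSF1R did rise, to 13.6 and 1.11 CPM, from 2.38 and 0.148 CPM in control. T cells in the stimulated cultures are argued against in the same way, with the highest gain of CD3D, CD3E and CD2 at 0 of CCR7's gain and no counts of CD3D and CD2 in any library. Of the T cell list, LCK and LAT did rise, from 129 and 3.05 CPM in control to 246 and 11.7 CPM.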

How the results depend on the processing

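No gene called in 1 direction was called in the other under any of the 13 alternatives to the gene test. Under DESeq2, 2500 of the 2707 risen and 2231 of the 2320 fallen genes were called again, and under limma-voom 2648 and 2304. Far fewer of them were called again with either control library left out. Of 75 named genes that passed, 73 kept direction and call under every alternative that was run, and the other 2 were NDUFS1 and NDUFV2. Most named genes were chosen for large changes or small p in this same fit, so their stability says little about other genes. The number of genes changed at least 2-fold was 2525, and 1681 with at least 5 CPM in 2 libraries, where fewer genes were tested (9743). With an estimated correlation, camera called 5 lists in place of 16. Leaving out 1 library at a time gave 1755 to 3885 higher and 1187 to 3698 lower genes; the lone library of a group was then assumed to vary like the other group, and the low values came from leaving out a control library and the high ones from leaving out a stimulated library. Without a stimulated library, the spread comes from the control pair alone, which differed less. The replicate number as a replicate block gave 2843 higher and 2377 lower genes; the 2 pairs deviated with a correlation of −0.012, so the numbers were not taken to pair the samples. With that block the germinal-centre list was called (adjusted p = 0.0263) and the glycolysis list was not (0.0676). The plasma cell list turned to the lower side under limma-voom (adjusted p = 0.738), and its camera adjusted p was 0.338 to 0.81 with single libraries left out. The T cell list turned under the replicate block (adjusted p = 0.934) and without control replicate 2 (0.830; leave-one-out range 0.547 to 0.905), and had no value with at least 5 CPM in 2 libraries, where too few members were left. The cause was not tested. Fry, which asks whether the genes of a list move on balance and does not compare them with other genes, gave adjusted p = 0.0304 (higher) for the plasma cell list, 0.0285 (higher) for the cholesterol list and 0.071 (lower) for the glycolysis list. The GC correction, added after the data were seen, gave 3465 higher and 3017 lower genes. In the simulation, which changed far fewer genes than passed here, 26% of changes of 1.5-fold were recovered. The adjusted threshold was harder to reach there, so that share does not give the recovery in these data.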

Other observations

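The 6 gene groups below were chosen after the values were seen, so their tests describe these libraries and are not independent evidence. All 6 measured APOBEC3 genes, which encode cytidine deaminases that restrict viruses, rose (median log2 fold change 5.06, or 3.94 with the 2 members at 0 in control set to their lower bound, camera adjusted p = 8.73e-10 over the 6 groups, and adjusted p = 0.0924 with an estimated correlation). APOBEC3G went from 3.23 to 72.2 CPM and APOBEC3F from 0.352 to 17.6 CPM. Members of this family resemble each other in sequence, so reads can be split between them. Of 16 JAK and STAT pathway genes 14 rose and none fell (median 1.43, camera adjusted p = 2.59e-10, and adjusted p = 0.063 with an estimated correlation), with JAK3 from 1.81 to 38.8 CPM, IL2RG from 21.0 to 126 CPM and STAT5A from 24.8 to 107 CPM, while IL4R and STAT5B did not pass. Of 20 TNF receptor superfamily and adaptor genes 10 rose, among them TRAF4 (log2 fold change 1.51 ± 0.12 SE), and TNFRSF17 (−1.005 ± 0.29) and CD27 (−1.598 ± 0.14) fell (median 0.76, camera adjusted p = 4.62e-08, and adjusted p = 0.063 with an estimated correlation).

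Of 24 cytoskeleton genes 15 rose and none fell (median 0.73, camera adjusted p = 1.08e-06, and adjusted p = 0.063 with an estimated correlation). Most are genes of the actin cytoskeleton, but VIM, with the largest rise of the group, encodes an intermediate filament protein. ACTB went from 7610 to 16918 CPM and LCP1 from 2527 to 5090.4 CPM. Of 13 trafficking and egress genes 7 rose, including GPR183, from 0.214 to 33.2 CPM, and S1PR2 (−0.46 ± 0.11) and ITGB7 (−1.14 ± 0.14) fell (median 2.25, camera adjusted p = 2.38e-04, and adjusted p = 0.132 with an estimated correlation). Of 20 chromatin regulators mutated in B cell lymphoma 14 did not pass, and camera gave no call (adjusted p = 0.341). DNMT3A, a DNA methyltransferase, went from 4.87 to 63.3 CPM and TET2, which opposes DNA methylation, from 0.627 to 8.95 CPM, BCOR rose by 0.56 ± 0.13 on the log2 scale, and SUZ12 (−0.64 ± 0.12) and SMARCA4 (−0.65 ± 0.17) fell.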
